A study of Rattus norvegicus with 6 samples.

How the data were processed

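RNA was sequenced from 6 male rats, 3 controls and 3 with painful diabetic neuropathy (PDN), the pain and sensory loss that can follow diabetes. The labels call the tissue of every sample sensory neuron, and the series title speaks of the dorsal root ganglion, the cluster of sensory neuron cell bodies beside the spinal cord. Per the labels' protocols, RNA was extracted with Trizol, 1 µg of total RNA entered each library, and the libraries were strand-specific and of the kind made for long noncoding RNA. The series' design text counts 3 rats per group, so a library is taken here as an animal. How diabetes was induced, the age of the rats and the hour of tissue collection are not given in the sources used here.

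The deposited data are 2 tables of 22536 genes, of which 22245 have an Ensembl identifier and 291 are assembled loci without one. One table holds FPKM (fragments scaled to the length of the transcript and the size of the library) as the authors deposited it, with a gene name and a locus for each gene. The aligner, the quantifier, the annotation and the genome build are not given in the sources used here, so loci are printed as the file gives them, without a build. The other deposited table is named for read counts, but its whole numbers were treated as a score, because they do not have the properties of counts. Among genes whose value exceeded 1000 in a library, 54.7% to 55.1% had a value equal, within a relative tolerance of 0.001, to the FPKM times the genomic span of the gene times 1 constant per library. The remaining values lay below that product, and none lay above it. The library totals of this table were 573396748 to 684759626. The constants correspond to 51856000 to 62786000 fragments per library behind the FPKM values, which is the only measure of depth that could be derived. No confidence interval for counting error was computed, since fragments per gene could not be recovered.

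The analysis fixed before the data were examined was a count model on the table named for read counts. As that table does not hold counts, the FPKM analysis planned beside it became the main test. Genes with an FPKM of at least 1 in at least 3 libraries (13282 genes) were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and the group as the only term. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with 0.05 as the threshold. Fold changes are PDN minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values. Levels are means ± SD over 3 libraries.

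A total of 43 gene lists, holding 816 distinct genes, were fixed before the data were examined. They cover pathways that bear on diabetic neuropathy and sensory neurons, and markers of the cell types a ganglion dissection can hold. Of these genes, 787 were found by name and 614 were tested. The 40 lists with at least 4 tested members were compared with all other genes by limma's camera with the preset correlation between genes of 0.01, adjusted over the 40 lists. Beside it, camera was run with a correlation estimated from the data, and fry, a rotation test of whether the members of a list move one way on balance. A list score is the mean of log2(FPKM + 1) over the tested members, centred on the 6 libraries.

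The genes to be named were set by a rule fixed before the data were examined. Its first part names, among genes past the threshold whose groups do not overlap, with a mean of at least 1 and a gene symbol other than a clone-type name, the 10 with the largest rise and the 10 with the largest fall. Where fewer than 5 pass in a direction, it names the 5 with the smallest p as values and not as changes. These 5 were also taken only from genes whose groups do not overlap, with a mean of at least 1 and such a symbol. Its second part names the 3 tested members with the smallest p in each called list and, in the other lists, members past the threshold over all genes. A further part names 20 genes of TLR4 signalling, inflammation, bile acid sensing, nociception and nerve injury whatever their p. The rule gave 72 genes, and 1 of the 20, Ly96, was not analysed here. Other genes that are named, also in the figures, were chosen after their values were seen, whether or not this is said beside them.

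The tests were tried on simulated data built on the 13282 genes and the spread of the real libraries. Of 100 genes changed by 1 on the log2 scale, 86 were recovered at the threshold, and of 100 changed by 2, 100 were recovered. There were 12 calls among unchanged genes, and 0 calls when nothing was changed. Both sets of genes were changed in the same simulated data, and many true changes make the adjusted threshold easier to pass. Recovery where few genes change was not simulated and would be lower, so these numbers do not give the power of the real comparison. Camera called all 3 lists that were shifted by 0.3, 1 list without shifted genes, and 1 list when nothing was shifted. This simulation gave genes independent noise, so it does not show how camera behaves when genes vary together.

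Alternatives planned before the data were examined and run here were a pseudocount of 0.1, leaving out each library in turn, an unadjusted threshold, a minimum fold, camera with an estimated correlation, fry, and lists without the member with the largest change. Alternatives chosen after the data were seen were 2 filters on low values, 2 scalings between libraries, a replicate block on FPKM, array weights, robust empirical Bayes, the whole-number table scaled to its total, the muscle score as a covariate, and leaving out the 2 libraries richest in muscle RNA. The planned count models and count normalizations were not run. Calculations and plots also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.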

Results

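Gene expression was measured by RNA sequencing in sensory tissue of 3 control rats and 3 rats with painful diabetic neuropathy (PDN). The FPKM values of each library rest on 51856000 to 62786000 fragments, as far as the deposited tables show it, and 13093 to 13286 genes per library had an FPKM of at least 1. The 10 most abundant genes took 6.08% to 7.25% of the FPKM of a library.

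The libraries were alike across the groups. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.977 to 0.984 within controls, 0.981 to 0.983 within PDN and 0.976 to 0.985 between the groups. The first principal component held 31.3% of the variance and set control 2 (24.01) and PDN 3 (10.75) apart from the other 4 libraries, which lay between -12.55 and -2.131. These 2 libraries also had the highest levels of skeletal muscle genes. Acta1, the actin of skeletal muscle, was at 193 FPKM in control 2 and 68.8 in PDN 3, at 13.3 in PDN 1, and at 1.11 to 1.35 in the other 3 libraries. Ckm, the creatine kinase of muscle, was at 97.5 FPKM in control 2, 31.7 in PDN 3 and 5.59 in PDN 1, against 0.334 to 0.498 in the others. All 11 tested genes of the muscle list were highest in control 2.

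The first comparison asked which genes differ between PDN and control tissue. Aldh18a1, which makes a precursor of proline, had the smallest p among named genes higher in PDN, at 4.21 ± 1.18 FPKM against 0.804 ± 0.197 in controls (SD, n = 3 each), a log2 fold change of 1.51 ± 0.17 (SE). Its adjusted p in limma was 0.229, so this difference did not pass the threshold. The DNA repair gene Mgmt was at 9.20 ± 1.20 against 4.90 ± 0.636 FPKM, the co-repressor gene Rcor3 at 5.71 ± 0.244 against 3.18 ± 0.549, Plekha1 at 32.2 ± 1.92 against 23.6 ± 0.769, and the phosphodiesterase gene Pde1c at 24.1 ± 1.07 against 18.6 ± 0.618. On the lower side in PDN, the sialyltransferase gene St3gal6 was at 7.80 ± 0.270 against 13.1 ± 1.70 FPKM, Igfbp3, which binds insulin-like growth factors, at 5.07 ± 0.0712 against 7.79 ± 0.721, and Cx3cl1, the chemokine fractalkine, at 1.24 ± 0.144 against 2.30 ± 0.168. Myom3, a gene of the sarcomere, was at 0.665 ± 0.0647 against 1.57 ± 0.0502 FPKM, and Sptlc2, a subunit of the enzyme that starts sphingolipid synthesis, at 27.4 ± 2.67 against 37.8 ± 1.61. These 10 genes were taken only from genes whose 3 libraries of one group lay above the 3 of the other, so that separation is no finding. None passed the adjusted threshold in limma, with adjusted p-values of 0.229 to 0.594. St3gal6 had a log2 fold change of -0.67 in FPKM but 0.05 in the whole-number table.

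Across the 13282 genes tested with limma, 0 passed an adjusted p of 0.05 in either direction, and the smallest adjusted p was 0.0737. At an unadjusted p under 0.05 there were 627 genes, 243 higher and 384 lower in PDN, where 664 would be expected with no effect. Groups that did not overlap were found in 1319 genes (9.93%), and chance gives 10%. Genes named below for a small p tend to separate in this way, so their separation adds no support. The share of higher genes among the 627 was 38.8%, and it was 49.5% with median-of-ratios scaling and 48.2% with upper-quartile scaling. The count of 0 became 1 without the filter or with robust empirical Bayes (AABR07012079.1), 2 in the whole-number table (Myom3 and Vps33a) and 9 when control 2 and PDN 3, the libraries richest in muscle RNA, were both left out. It was 3 without control 1, 2 without control 3, 4 without PDN 1, 6 without PDN 3, and 0 without control 2 or PDN 2. Splits of the 6 libraries into 3 and 3 that mixed the groups also called 1 to 6 genes.

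The series title names TLR4, the receptor for bacterial lipopolysaccharide, and the second comparison asked whether its gene differs. Tlr4 (ENSRNOG00000010522, chromosome 5, 82587420 to 82601052 as the file gives it) was at 4.99 ± 0.692 FPKM in PDN and 5.31 ± 0.357 in controls (SD, n = 3 each). Its log2 fold change was -0.08 ± 0.11 (SE), with a 95% interval of -0.329 to 0.169 and an adjusted p of 0.999 in limma. Without PDN 1 the fold change was 0.006. The adaptor gene Myd88 was at 2.77 ± 0.272 against 2.77 ± 0.108 FPKM, and the sign of its difference turned with the scaling. The NF-kB subunit genes Nfkb1 (9.98 ± 0.729 against 10.4 ± 0.335) and Rela (9.06 ± 1.19 against 9.60 ± 0.860) also differed by less than the spread between replicates. Among 22 tested genes from TLR4 to NF-kB, 18 had a lower and 4 a higher estimate in PDN, with a median log2 fold change of -0.07, and the list did not pass camera (adjusted p = 0.0608). Of its members, Relb (2.13 against 3.45 FPKM) and Tab1 (7.92 against 8.93 FPKM), chosen after their values were seen, were lower at an unadjusted p under 0.05, and 0 members passed adjusted over the list alone.

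**Figure D1:**
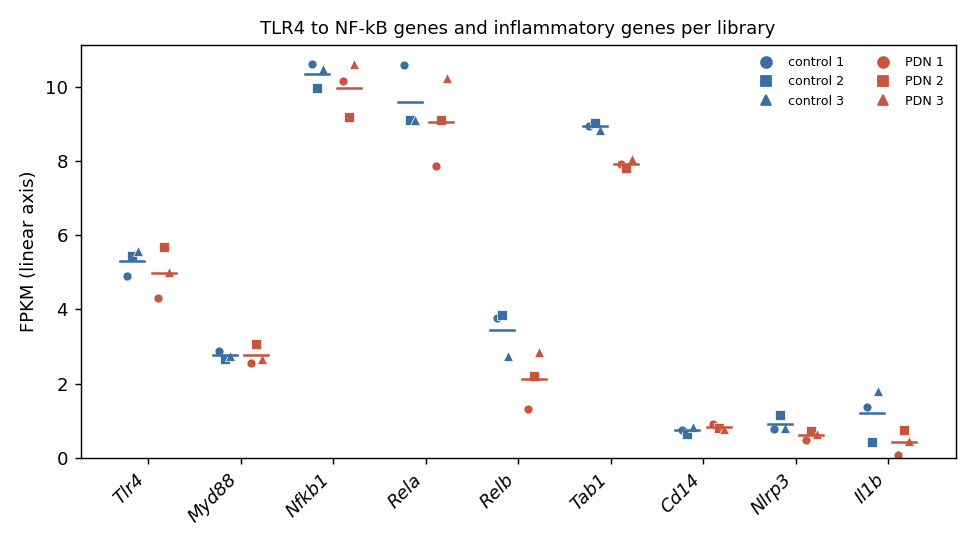
FPKM (vertical linear axis) of TLR4 pathway and inflammatory genes (horizontal axis) in each library, with controls in blue, PDN in red, marker shape for the replicate number and a line at each group mean. The groups overlap for Tlr4, Myd88, Nfkb1 and Rela, while the 3 PDN libraries lie below the 3 controls for Tab1 and for Nlrp3, which was not tested.

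Inflammatory genes of the third part of the rule had an FPKM under 1 in most libraries and stayed below the filter, so they have values and no test. Il1b ranged from 0.0808 to 1.81 FPKM over the 6 libraries, with 1.20 ± 0.701 in controls and 0.426 ± 0.334 in PDN (SD, n = 3 each). Nlrp3, the sensor of an inflammasome, was at 0.914 ± 0.203 in controls and 0.615 ± 0.122 in PDN, and Cd14, the co-receptor of TLR4, at 0.742 ± 0.0990 and 0.830 ± 0.0693. For Nlrp3 the groups did not overlap, at no less than 0.779 in controls and no more than 0.719 in PDN. Il6 did not exceed 0.11 FPKM in any library. Tnf was listed at 0 in 5 libraries and Gpbar1, the membrane receptor for bile acids, in 4, with highest values of 0.117 and 0.0779. The nuclear bile acid receptor gene Nr1h4 reached at most 0.232 FPKM. The list of 9 tested inflammasome and inflammatory enzyme genes had a median log2 fold change of -0.16 (camera adjusted p = 0.26), and the 13 tested bile acid genes had a median of -0.09 (camera adjusted p = 0.139).

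The third comparison asked whether the gene lists differ as groups. With the preset correlation, camera called 15 of the 40 lists, 6 higher and 9 lower in PDN. The counts were 3 higher and 7 lower without control 2, 3 and 8 without PDN 1, and 8 and 13 without PDN 3. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.198. The estimate was 0.48 for glucocorticoid-responsive genes, 0.297 for macrophages, 0.687 for pericytes and 0.743 for red blood cells, against the preset 0.01. It was -0.0292 for the clock and -0.00657 for fibroblasts. Splits of the 6 libraries into 3 and 3 that mixed the groups also called 7 to 17 lists with the preset value. A call with the preset value alone is therefore weak evidence of a group difference. Fry called 1 list, the circadian clock. No member of any list passed the threshold over all genes, and 10 lists had at least 1 member that passed adjusted over the list alone. The adjustment over a list alone is not corrected for the number of lists and depends on which genes share the list. A pass by it is therefore weaker than one over all genes.

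**Figure D2:**
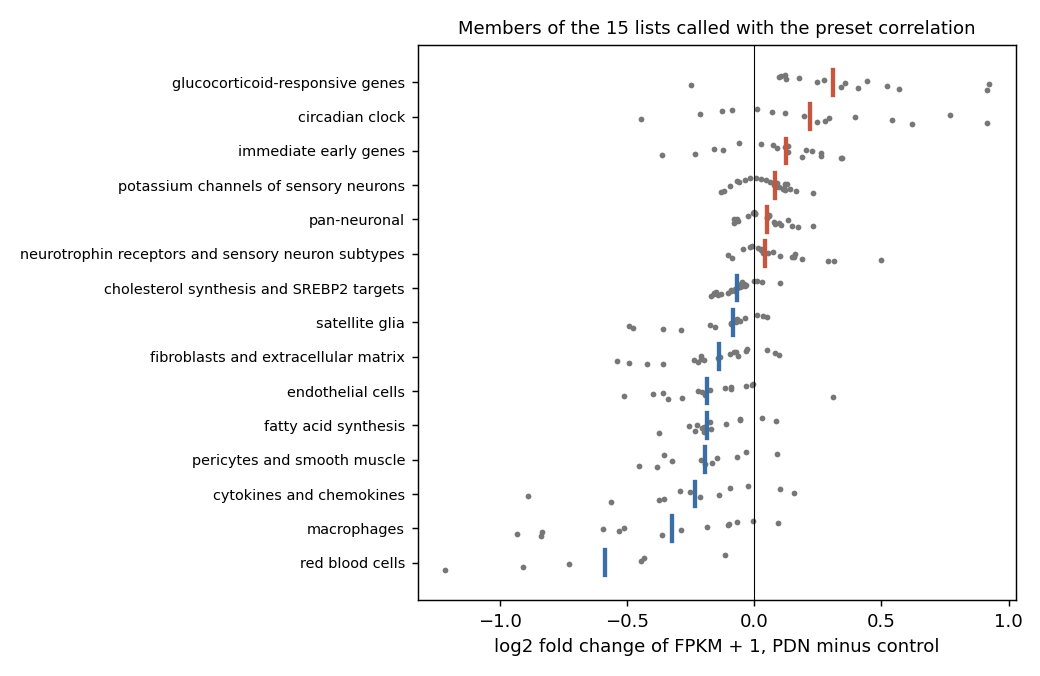
Log2 fold change of FPKM + 1, PDN minus control (horizontal axis), of each tested member (grey points) of the 15 lists that camera called with the preset correlation (vertical axis), with a bar at the list's median, red above 0 and blue below. Medians run from -0.585 for red blood cell genes to 0.308 for glucocorticoid-responsive genes.

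Genes of the circadian clock, the transcription loop that keeps daily time, were higher in PDN as a list, with 12 of 16 tested members higher and a median log2 fold change of 0.22 (camera adjusted p = 3.35e-06; adjusted p = 0.198 with an estimated correlation; fry adjusted p = 0.0426). Adjusted over the list alone, 6 members were higher (Per1, Per2, Per3, Tef, Nr1d1 and Wee1) and 1 was lower (Arntl), and over all genes 0 passed. Of these, Per3, Nr1d1, Wee1 and Arntl were chosen after their values were seen. Per1, a repressor in the loop, was at 8.53 ± 2.86 FPKM in PDN against 3.95 ± 0.698 in controls (SD, n = 3 each), and Per2 at 2.29 ± 0.131 against 1.16 ± 0.337. Tef, an output gene of the clock, was at 28.2 ± 0.783 against 23.6 ± 0.468 FPKM. Arntl, which encodes the activator BMAL1, went the other way, at 2.69 ± 0.188 FPKM in PDN against 4.08 ± 0.965. The call held when each library was left out in turn, with a highest adjusted p of 0.000266.

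**Figure D3:**
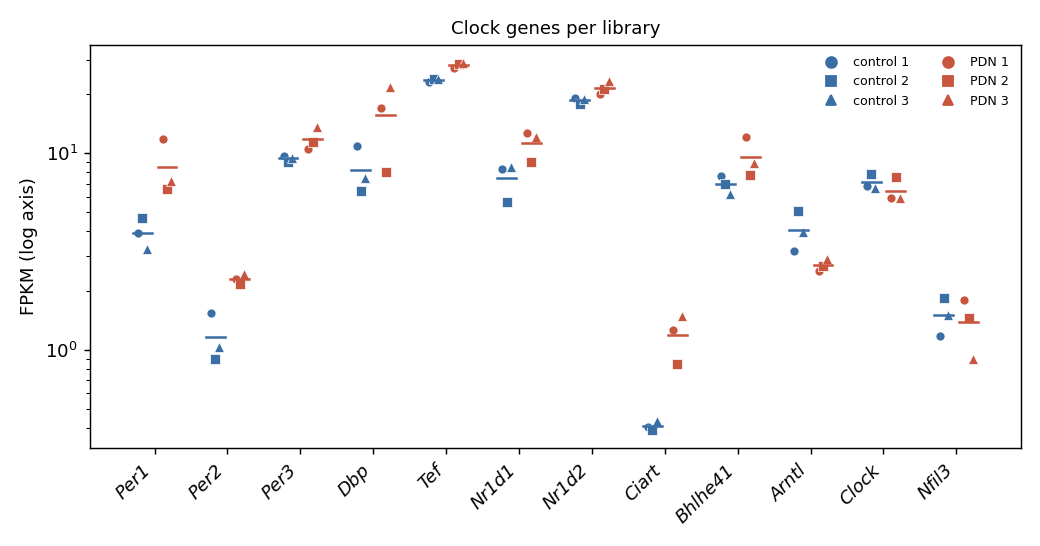
FPKM (vertical log axis) of clock genes (horizontal axis) in each library, with controls in blue, PDN in red, marker shape for the replicate number and a line at each group mean. The 3 PDN libraries lie above the 3 controls for Per1, Per2, Per3, Tef, Nr1d1, Nr1d2, Ciart and Bhlhe41 and below them for Arntl. The groups overlap for Dbp, Clock and Nfil3.

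Glucocorticoid-responsive genes were higher in PDN as a list, with 15 of 16 tested members higher and a median log2 fold change of 0.31 (camera adjusted p = 2.5e-06; adjusted p = 0.631 with an estimated correlation). Mt2A, a metallothionein gene, was at 8.45 ± 2.0 FPKM in PDN against 5.28 ± 0.444 in controls (SD, n = 3 each), and the cell cycle inhibitor gene Cdkn1a at 4.07 ± 0.849 against 2.80 ± 0.351. Per1, which this list shares with the clock list, was the 1 member that passed adjusted over the list alone. The list score was 0.602 in PDN 1, -0.0288 in PDN 2 and -0.0683 in PDN 3, against -0.226 to -0.11 in controls. Without PDN 1 the median was 0.0453, with a camera adjusted p of 0.049. Immediate early genes, which respond within minutes to stimulation, had 13 of 18 members higher and a median of 0.13 (camera adjusted p = 0.0205; adjusted p = 0.705 with an estimated correlation). Among them Dusp1 was at 8.55 ± 1.39 against 6.51 ± 0.715 FPKM, Klf2 at 3.60 ± 0.795 against 2.61 ± 0.512 and Jund at 56.4 ± 2.47 against 49.6 ± 6.44. That call was lost without control 2, control 3, PDN 1 or PDN 2, without the filter, and with the stricter filter. The median of immediate early genes ran from 0.0366 to 0.199 when each library was left out.

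Macrophage markers were lower in PDN as a list, with 13 of 14 tested members lower and a median log2 fold change of -0.32 (camera adjusted p = 1.7e-05; adjusted p = 0.631 with an estimated correlation). The fractalkine receptor gene Cx3cr1 was at 1.45 ± 0.469 FPKM in PDN against 3.39 ± 0.901 in controls (SD, n = 3 each), and the growth factor receptor gene Csf1r at 7.25 ± 0.643 against 9.60 ± 0.608. These were the 2 members that passed adjusted over the list alone. Adgre1, which encodes the marker F4/80, was at 2.45 ± 0.467 against 5.97 ± 2.91 FPKM, and its 3 PDN values lay below the 3 control values. It was named for its small p, so that separation is no finding. The complement genes C1qa (6.89 against 7.29 FPKM) and C1qb (3.47 against 3.08), chosen after their values were seen, and Mrc1 (4.04 against 3.87), likewise chosen, differed by less than their spread. The call held when each library was left out, with a highest adjusted p of 0.0105.

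Red blood cell genes moved the same way, with 6 of 6 tested members lower and a median of -0.59 (camera adjusted p = 0.000741; adjusted p = 0.631 with an estimated correlation). The haemoglobin gene Hbb was at 45.1 ± 18.3 FPKM in PDN against 82.8 ± 18.7 in controls, Hbb-b1 at 7.19 ± 4.03 against 17 ± 4.12, and Hba-a1 at 66.9 ± 30.7 against 105 ± 21.6 (SD, n = 3 each). Hbb and Hbb-b1 passed adjusted over the list alone. Haemoglobin genes have near-identical copies, so the split of fragments between them is uncertain. The list score was 0.225 in PDN 2, within the control range of 0.0304 to 0.621, and -0.431 and -0.753 in PDN 1 and PDN 3. The call was lost without control 1 (adjusted p = 0.0533).

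Cytokine and chemokine genes had 10 of 12 tested members lower and a median of -0.23 (camera adjusted p = 0.0124; adjusted p = 0.538 with an estimated correlation). Cx3cl1 was the 1 member that passed adjusted over the list alone. Cxcl16 was at 5.60 ± 0.883 FPKM against 7.53 ± 0.692 in controls and Cxcl12 at 7.94 ± 2.41 against 10.2 ± 1.01 (SD, n = 3 each). The call was lost without control 1, without PDN 2, without the filter and with the stricter filter. Its median ran from -0.299 to -0.0709 when each library was left out.

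Genes of fibroblasts and extracellular matrix were lower in PDN as a list, with 17 of 20 tested members lower and a median of -0.14 (camera adjusted p = 0.00024; adjusted p = 0.208 with an estimated correlation). The collagen genes Col6a2 (8.96 ± 0.369 against 11.8 ± 0.717 FPKM) and Col3a1 (42.4 ± 9.16 against 59.2 ± 1.35) and the proteoglycan gene Lum (21.8 ± 3.48 against 29.3 ± 0.945) had the smallest p, and Col6a2 passed adjusted over the list alone. Endothelial genes had 15 of 16 members lower and a median of -0.18 (camera adjusted p = 0.00614; adjusted p = 0.705 with an estimated correlation). The junction gene Cdh5 was at 4.98 ± 0.587 against 6.26 ± 0.441 FPKM and Egfl7 at 2.35 ± 0.420 against 3.21 ± 0.264, whereas Cldn5, a tight junction gene of the same list, was at 26.8 ± 1.32 against 21.6 ± 3.40. Pericyte and smooth muscle genes had 10 of 11 members lower and a median of -0.19 (camera adjusted p = 0.00614; adjusted p = 0.705 with an estimated correlation), with Pdgfrb at 6.36 ± 0.908 against 8.59 ± 1.35 FPKM, Acta2 at 11 ± 2.78 against 15.2 ± 2.05 and Myh11 at 4.79 ± 0.404 against 5.65 ± 0.807. Satellite glia, the cells that wrap sensory neuron bodies, had 13 of 16 marker genes lower and a median of -0.08 (camera adjusted p = 0.00614; adjusted p = 0.705 with an estimated correlation). Their potassium channel gene Kcnj10 was at 29.0 ± 3.40 against 35.5 ± 2.61 FPKM, Gfap at 4.31 ± 1.04 against 6.39 ± 1.45 and Ptprz1 at 15.7 ± 2.92 against 20.2 ± 1.37. The fibroblast call held when each library was left out. The endothelial, pericyte and satellite glia calls were lost without control 2, which was rich in muscle RNA, and without PDN 1, and the endothelial call also with both muscle-rich libraries left out and with the stricter filter, while the pericyte call was lost with array weights. Over the leave-one-out fits the medians ran from -0.233 to -0.105 (endothelial), -0.24 to -0.0817 (pericyte) and -0.132 to -0.0386 (satellite glia).

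Fatty acid synthesis genes were lower in PDN as a list, with 12 of 14 tested members lower and a median of -0.19 (camera adjusted p = 5.55e-05; adjusted p = 0.538 with an estimated correlation). The desaturase genes Scd (75.4 ± 8.26 against 97.6 ± 1.41 FPKM) and Scd2 (919 ± 59.9 against 1080 ± 62.2) and the elongase gene Elovl5 (156 ± 10.4 against 179 ± 3.84) were each lower in all 3 PDN libraries than in all 3 controls (SD, n = 3 each). They were named for the smallest p in the list, so that separation is no finding. Scd passed adjusted over the list alone. The list score ran from 0.05 to 0.108 in controls and was -0.15, -0.0871 and 0.00788 in PDN 1, PDN 2 and PDN 3. The satellite glia score had the same highest and lowest libraries, at 0.182 in control 2 and -0.164 in PDN 1. So did the scores of endothelial cells (0.27 and -0.237), pericytes and smooth muscle (0.348 and -0.358) and Schwann cells (0.202 and -0.129). The call held when each library was left out, with a highest adjusted p of 0.00154. Cholesterol synthesis genes had 22 of 25 members lower and a median of -0.07 (camera adjusted p = 0.0155; adjusted p = 0.705 with an estimated correlation). Nsdhl was at 20.3 ± 1.55 against 22.9 ± 1.31 FPKM, Pmvk at 30.0 ± 2.18 against 33.2 ± 1.96 and Stard4 at 12.2 ± 0.945 against 13.8 ± 1.12. This call was lost without control 2, control 3, PDN 1 or PDN 3, and with both muscle-rich libraries left out.

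Neuronal lists had small positive medians. Neurotrophin receptors and markers of sensory neuron subtypes had 15 of 20 members higher and a median of 0.04 (camera adjusted p = 0.00614; adjusted p = 0.631 with an estimated correlation). In this list Fxyd2, a subunit of the sodium pump, was at 47.0 ± 3.88 FPKM in PDN against 37.6 ± 2.28 in controls, Necab2 at 1.86 ± 0.228 against 1.34 ± 0.114 and Calb1 at 3.32 ± 0.996 against 2.05 ± 0.670 (SD, n = 3 each). Pan-neuronal genes had 15 of 21 members higher and a median of 0.05 (camera adjusted p = 0.0468; adjusted p = 0.705 with an estimated correlation), with Map2 at 108 ± 4.27 against 92.1 ± 12.8 FPKM, Isl1 at 22.5 ± 1.03 against 19.8 ± 1.41 and Avil at 238 ± 11.2 against 215 ± 16.6. Potassium channel genes had 17 of 24 members higher and a median of 0.08 (camera adjusted p = 0.0272; adjusted p = 0.705 with an estimated correlation). Its members with the smallest p went both ways, with Kcnn2 at 3.50 ± 0.256 against 2.85 ± 0.460 FPKM, Kcnip4 at 23.8 ± 2.11 against 26.1 ± 1.30 and Kcnd3 at 23.4 ± 1.21 against 25.5 ± 2.04. These 3 calls were lost without control 2, where the pan-neuronal median turned to -0.02, and without PDN 1, and the potassium channel call also without control 1. The pan-neuronal and potassium channel calls were lost with both muscle-rich libraries left out, without the filter, with array weights and without the member with the largest change, and the potassium channel call with the stricter filter.

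No list of pain sensing or nerve injury genes was called, and no member passed over all genes. The heat-gated channel gene Trpv1 was at 52.3 ± 2.73 FPKM in PDN and 51.5 ± 4.32 in controls, and the sodium channel genes Scn9a at 84.9 ± 3.73 and 82.3 ± 8.42 and Scn10a at 118 ± 11.9 and 120 ± 15.8 (SD, n = 3 each). The neuropeptide genes Calca (598 ± 111 and 600.5 ± 15.8) and Tac1 (164 ± 11.8 and 181 ± 4.4), the injury gene Atf3 (4.23 ± 1.38 and 3.27 ± 0.301) and the growth cone gene Gap43 (50.7 ± 1.08 and 49.4 ± 5.64) had adjusted p-values of 0.999 in limma. Sprr1a, another injury gene, was listed at 0 in all 6 libraries. The 27 nociceptor ion channel genes had a median log2 fold change of 0.03, the 21 nerve injury genes -0.01, with a sign that turned with the scaling, the 13 neuropeptide genes -0.02 and the 19 genes of opioid, cannabinoid and other inhibitory receptors 0.03. In the nociceptor list the irritant receptor gene Trpa1 had the smallest p, at 24.6 ± 4.04 FPKM in PDN against 32.5 ± 3.18 in controls (SD, n = 3 each), with groups that did not overlap and an adjusted p of 0.435 over the list alone in limma. P2rx2 (1.87 ± 0.327 against 1.32 ± 0.101) and Piezo1 (1.86 ± 0.178 against 2.35 ± 0.264) also had groups that did not overlap and did not pass. These 3 genes were chosen after their values were seen. Adjusted over the list alone, Bdnf (-0.33) and Gal (-0.46) were lower among neuropeptides, though they did not pass in the nerve injury list, which also holds them, and the cannabinoid receptor gene Cnr1 (0.41) was higher among inhibitory receptors, all chosen after their values were seen, and Igfbp3 was lower among the 22 insulin and IGF signalling genes, whose median was -0.02.

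The 25 lists that were tested and not called had camera adjusted p-values of 0.0608 to 0.99. Of the immune lists, MHC class II genes had a median of 0.27, complement genes -0.10 and interferon-stimulated genes 0.01. With both muscle-rich libraries left out, the interferon list had a median of -0.13 and an adjusted p of 0.0145. Medians of metabolic lists were 0.01 for glycolysis, 0.01 for the polyol and hexosamine pathway, -0.02 for fatty acid oxidation, 0.01 for the mitochondria-encoded and -0.04 for the nuclear-encoded respiratory chain. Stress lists had medians of -0.06 for heat shock, -0.05 for NRF2 targets and 0.02 for the unfolded protein response, and cell cycle genes had -0.05. Among cell types, the medians were -0.03 for Schwann cells and myelin, -0.05 for spinal cord glia, -0.05 for bone and cartilage, 0.11 for adipocytes and -0.03 for skeletal muscle. The skeletal muscle list had a median of 0.62 and a camera adjusted p of 1.92e-05 with both muscle-rich libraries left out. That difference rested on PDN 1, whose muscle score was -0.0756, against -1.53 in PDN 2, -1.52 in control 1 and -1.57 in control 3. The skeletal muscle, fatty acid oxidation, bone and nuclear-encoded respiratory chain lists had a negative median but an upward direction in camera, and in all of them but bone the mean was above 0. For glycolysis the mean was below 0, and for NRF2 targets above 0, against their medians. Mast cell, neutrophil and lymphocyte lists had 1 tested member each and were not tested, with log2 fold changes of -0.07, -0.25 and -0.38.

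**Figure D4:**
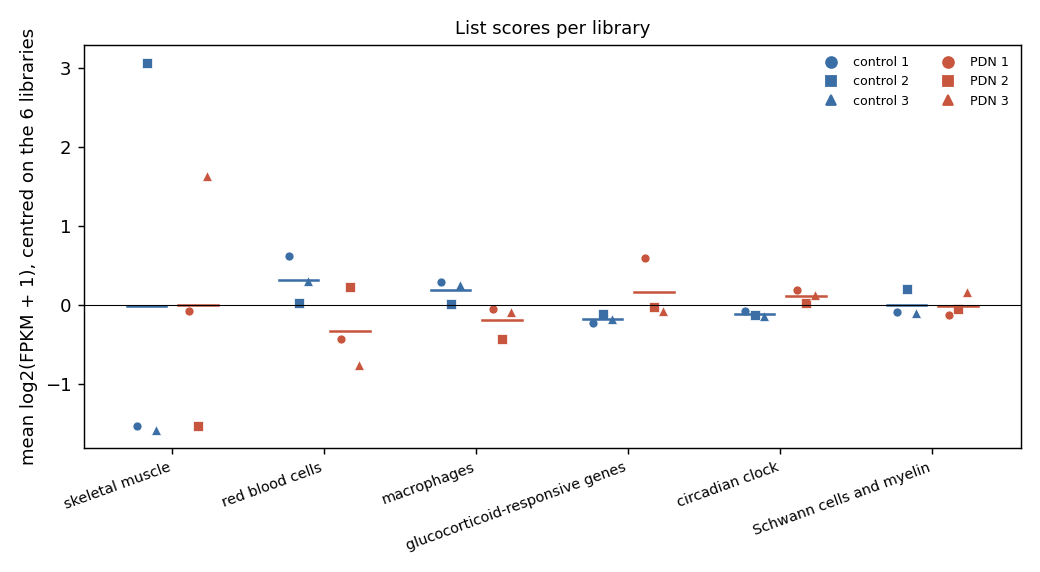
List scores, the mean log2(FPKM + 1) of the tested members centred on the 6 libraries (vertical axis), for 6 lists (horizontal axis), with controls in blue, PDN in red, marker shape for the replicate number and a line at each group mean. The muscle score stands out in control 2 (3.06) and PDN 3 (1.63), and the glucocorticoid score in PDN 1 (0.602).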

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

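All alternatives were chosen after the data were seen except the pseudocount of 0.1, the leave-one-out fits, the unadjusted and minimum-fold thresholds, the estimated correlation, fry and the lists without their largest member. The planned count models, count normalizations and count filters were not run, because the table they needed does not hold counts. The count of 0 changed genes became 1 without the filter, 1 with robust empirical Bayes, 2 in the whole-number table, 9 with both muscle-rich libraries left out and 627 at an unadjusted p, and it was 0 to 6 when each library was left out. It stayed 0 with the other pseudocount, the stricter filter, both scalings, array weights, the muscle covariate and a minimum log2 fold change of 1. At an unadjusted p, 396 genes were higher without the filter (243 in the main analysis), and 137 were higher and 237 lower with the stricter filter, which tests fewer genes (9222); the lower count ran from 239 to 522 when each library was left out. The 15 called lists became 0 with an estimated correlation and 1 with fry. Tlr4 ran from -0.161 to 0.00595 when each library was left out, positive without PDN 1. Of the 15 lists, 5 (clock, glucocorticoid, macrophage, fibroblast and fatty acid synthesis) kept their call in all 6 leave-one-out fits. These fits used the preset correlation and share most of their libraries, so keeping a call does not test that setting. With all 6 libraries and an estimated correlation, these 5 lists had camera adjusted p-values of 0.198 to 0.631.

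The samples share replicate numbers, but nothing in the labels says that a number marks a pair, and the deviations of same-numbered libraries from their group means correlated by 0.171, -0.12 and -0.0865 across genes, so the numbers were not taken as pairs. With a replicate block 0 genes were called, 849 were at an unadjusted p under 0.05 (329 higher, 520 lower) and 15 lists were called. Only the libraries numbered 1 correlated best with their own number.

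The signs of some results turned, and the cause was not tested. In the whole-number table St3gal6 was at 0.0505, Myd88 at 0.00423, the skeletal muscle list at 0.0535 and spinal cord glia at 0.00475. Myd88 was at 0.0142 and nerve injury at 0.00473 with median-of-ratios scaling, and at 0.0118 and 0.00187 with upper-quartile scaling. With array weights Myd88 was at 0.00391, nerve injury at 0.00277, Schwann cells at 0.00737, bone at 0.0241, skeletal muscle at 0.343 and the polyol pathway at -0.00214. Skeletal muscle was at 0.565 with a pseudocount of 0.1 and at 0.269 with the stricter filter, which also put neuropeptides at 0.0182. Without the filter adipocytes were at -0.00489 and spinal cord glia at 0.0328. With both muscle-rich libraries left out Trpv1 was at -0.0245, Schwann cells at 0.0188, interferon-stimulated genes at -0.133, the nuclear-encoded respiratory chain at 0.0266, nociceptor channels at -0.0439, skeletal muscle at 0.615 and the unfolded protein response at -0.0214. Without their largest member the mitochondria-encoded respiratory chain was at -0.00948, spinal cord glia at 0.0351 and the unfolded protein response at -0.0218.

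Signs also turned when single libraries were left out. Gene ranges were -0.0589 to 0.0388 for Myd88, -0.135 to 0.0384 for Scn10a, -0.0303 to 0.0873 for Trpv1, -0.0137 to 0.126 for Scn9a, -0.0197 to 0.131 for Gap43, -0.163 to 0.00853 for Rela, -0.092 to 0.00279 for Nfkb1 and -0.13 to 0.136 for Calca. List medians ran from -0.0589 to 0.0496 for the polyol pathway, -0.0658 to 0.0239 for the nuclear-encoded and -0.168 to 0.175 for the mitochondria-encoded respiratory chain, -0.125 to 0.113 for interferon-stimulated genes, -0.0426 to 0.0403 for nociceptor channels, -0.00587 to 0.0846 for inhibitory receptors, -0.0566 to 0.00705 for fatty acid oxidation, -0.0758 to 0.0308 for the unfolded protein response and -0.0215 to 0.105 for pan-neuronal genes. They ran from -0.0971 to 0.0668 for Schwann cells, -0.833 to 1.55 for skeletal muscle, -0.107 to 0.0254 for bone, -0.0659 to 0.00394 for nerve injury, -0.146 to 0.0137 for the cell cycle, -0.228 to 0.0648 for complement and -0.00691 to 0.0352 for glycolysis. Depth per gene could not be derived, so what it limits was not measured.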

Other observations

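The tests of clock phase, glucocorticoid exposure, neuronal share and muscle tissue, and the counts over other splits of the libraries, were chosen after the values they bear on had been seen. The camera test with the red blood cell covariate was written down before its value was seen, and the score difference beside it was added afterwards.

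Among clock genes below the filter, Ciart, a repressor of the clock, was at 0.389 to 0.432 FPKM in the 3 controls and at 0.84 to 1.48 in the 3 PDN libraries. The groups overlapped for Npas2, at 0.0663 to 0.363 in controls and 0.103 to 0.143 in PDN. Both were chosen after their values were seen. Dbp, an output gene of the clock, was at 8.05 FPKM in PDN 2, between the control values of 6.45 and 10.9, and at 16.9 and 21.8 in the other PDN libraries.

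Genes called when libraries were left out were often gene copies or unnamed loci. Leaving out 1 library at a time, or both muscle-rich libraries, called 19 different genes, 10 of them with clone-type names, and Rpl21 and Rpl23a, ribosomal protein genes with many near-identical copies, were among the rest. Asphd1, Rpl21, LOC100911615, LOC100911951 and LOC103689999 were the 5 genes called both without PDN 3 and with both muscle-rich libraries left out.

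The difference in clock genes may be a shift of clock phase between the groups. Genes that peak with Per and Dbp, whose rise prompted the question, were higher in PDN by 0.511 ± 0.121 (SE) in mean log2(FPKM + 1). The mean of the genes that should move against them, Arntl, Npas2, Clock and Nfil3, differed by -0.2 ± 0.114 (SE), within 2 standard errors. Its exact permutation p was 0.2, two-sided, where 3 against 3 allows no less than 0.1, and the groups overlapped in this mean. For the genes that peak with Per and Dbp the exact permutation p was 0.1, but their rise had prompted the question. Arntl itself did not overlap, at 2.51 to 2.89 FPKM in PDN against 3.17 to 5.09 in controls. Npas2, Clock and Nfil3 did, and Npas2 was below the filter. A shift of phase therefore stays open. Exposure to glucocorticoids, which also drive Per1, stays open too: the other glucocorticoid-responsive genes were higher by 0.298 ± 0.219 (SE), a difference that rests on PDN 1 (0.58, against -0.0417 and -0.0918 in PDN 2 and PDN 3 and -0.211 to -0.1 in controls). That difference had an exact permutation p of 0.1, the least that 3 against 3 allows, so it cannot pass 0.05. Of the 10 splits of the libraries into 3 and 3, 1, the real one, gave a fry p for the clock list as small as 0.00106, and the smallest of the others was 0.213, but 10 splits cannot give a share under 0.05. The labels give no hour of tissue collection, so collection at different hours and an effect of diabetes on the clock were not tested and remain open.

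The lower macrophage markers could reflect the makeup of the tissue sample and not only the state of the cells. Less blood in the PDN samples stays open as a cause. With the red blood cell score as a covariate the macrophage list had a camera adjusted p of 1.62e-05 and a score difference of -0.481 ± 0.223 (SE). Muscle in control 2 and PDN 3 stays open too, and with both left out these were 2.85e-09 and -0.517 ± 0.189 (SE). The macrophage score thus stayed lower in PDN by more than 2 standard errors in both checks, but with so few libraries that margin cannot decide. A larger neuronal share, which would dilute all other cells, cannot be told apart from a loss of macrophage transcripts, because the macrophage score minus the Schwann cell score differed by -0.365 ± 0.231 (SE) between the groups, within 2 standard errors. The pan-neuronal score differed by 0.046 ± 0.0659 (SE) and the Schwann cell score by -0.00991 ± 0.133 (SE), each by less than its standard error. These camera values use the preset correlation, with which 3 of the 10 splits gave an adjusted p for this list as small as the real 1.7e-05, the smallest of the others being 5.35e-06, and 10 splits cannot give a share under 0.05. Fewer macrophages, lower expression per macrophage and an effect of diabetes were not tested apart.

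The muscle genes in control 2 and PDN 3 may come from skeletal muscle taken with the tissue. Of the 11 tested muscle genes, 11 were highest in control 2, including the abundant Acta1 (193 FPKM), Myh1 (116) and Ckm (97.5), and the same genes were next highest in PDN 3, except Pvalb, which proprioceptive neurons also express and which was at 95.1 to 145 FPKM in all libraries. Control 2 and PDN 3 were also the highest libraries for pericytes and smooth muscle (scores of 0.348 and 0.155), Schwann cells (0.202 and 0.167) and endothelial cells (0.27 and 0.0286). Those scores were smaller than the skeletal muscle scores of 3.06 and 1.63. The fibroblast score was 0.151 in control 2 and -0.0576 in PDN 3. No biological explanation was tested, as the skeletal muscle score did not follow the groups (a difference of 0.0202 ± 1.79, SE).

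The same counts were made for all 10 splits of the libraries into 3 and 3. The real split called 0 genes at an adjusted p under 0.05 and the other splits called 1 to 6. Any of the 10 splits reaches a count of 0 whatever the data, so the real count cannot be tested against chance. The other splits show that counts of 1 to 6 also arose where the groups were mixed. At an unadjusted p under 0.05 the real split gave 627 genes, 4 of the 10 splits gave as many, and the highest of the others was 1292. Camera with the preset correlation called 15 lists in the real split, 3 of the 10 splits gave as many, and the others called 7 to 17. With 10 splits the share is never under 0.05.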
